A study of Homo sapiens with 2 samples.

How the data were processed

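The study sequenced RNA from the human gastric cancer line HGC-27, with 1 library from cells given a control peptide and 1 from cells given the peptide that the sample titles call SOS, both after 48 h. Per the labels' protocols, the cells grew in RPMI medium with serum, RNA was extracted with TRIZOL, its integrity was checked, and Illumina libraries were made. How messenger RNA was selected and whether the libraries kept strand are not given in the sources used here. Reads of a gene and of an overlapping or antisense partner are therefore uncertain.

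The data analysed are 1 table for the series. Per the file headers it holds FPKM (fragments per kilobase of transcript, scaled for depth) for each library, and the authors' log2 ratio, p-value, adjusted p-value and mark of significance. Per the submitters' processing notes, HISAT2, Cufflinks and RSEM were used with the genome build GRCh38.p10; versions and roles are not given in the sources used here. The test behind the deposited p-value and its adjustment are likewise not given. The deposited FPKM in each library were whole multiples of 1 small step for 99.5% of the values above 0 and below 100 (20758 values in control and 21477 in SOS), against 11.0% and 12.3% by chance at the tolerance used. TPM rounded to 2 decimals and multiplied by a constant would give such steps, so the FPKM hold no whole reads. On that reading the named genes hold 96.9% of the control library and 92.4% of the SOS library. The deposited log2 ratio behaved as a ratio of whole reads: of 3086 genes with FPKM under 0.3 in both libraries, 96.0% had the log2 of a ratio of whole numbers up to 20, within 0.0006, against 5.7% after random shifts of up to 0.1. It correlated with log2 of control over SOS FPKM across 9005 genes with FPKM of at least 5 in both (Pearson r = 0.93, across genes, which are not independent replicates), with a median offset of 0.152 that corresponds to a depth ratio of 1.11. The authors' ratio was 0 for 4342 of 4357 genes at 0 in exactly 1 library.

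Although the table is named for transcripts, it has 1 entry per gene. The planned comparison of transcript shares within genes was therefore not run, and values of entries that share a name were summed. Of 58233 named entries, 27 carried names that a spreadsheet had turned into dates and were left out, and 215 names stood on more than 1 entry. A further 412 entries had no gene name and were left out. The column of gene links matched the names in 0.583% of entries and was not used. Gene types, positions and transcript lengths come from the GENCODE release 29 annotation on GRCh38, matched by name for 96.6% of 56544 genes. The length and GC content of a gene are medians over all its annotated transcripts, which need not be those expressed. That release may differ from the one the authors used. Every column of values in the table was mapped to a library or to the authors' comparison.

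The depth of each library is not stated. It was estimated from genes with 1 annotated transcript of at least 1500 bases, seen in 1 library only at the commonest p of such genes, taken to be a single read, with 200 bases taken off for the fragment length. The median estimate was 2.94e7 fragments in control (quartiles 2.64e7 and 3.40e7, from 113 genes) and 2.56e7 in SOS (quartiles 2.31e7 and 2.86e7, from 160 genes). No interval for counting error was computed because the table gives no counts. A high FPKM need not mean many reads. USP41 and LRMDA had an authors' log2 ratio of exactly 1 in the deposited table. Very few reads would give such a value, but many reads in the same proportion would too. Neither gene had a deposited adjusted p under 0.001, while GDF15, with a ratio of -1, did. Few reads are therefore the likelier reading for both, though the test behind that p is not given. Differences between cultures are not measured by depth.

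The measure is log2((SOS FPKM + 1)/(control FPKM + 1)) for genes with an FPKM of at least 1 in either library, which understates the difference for genes of low level. Genes with an absolute log2 ratio of at least 1, a 2-fold difference on that scale, were counted in each direction. Folds printed beside FPKM are plain ratios of the 2 values. For 34 gene lists, the median over measured members was placed as a percentile among medians of 10000 random lists of the same size, drawn within 20 bins of mean expression, and a list in the outer 2.5% on either side was taken to stand apart. This describes these 2 libraries and is no test of the treatment. A list needed 3 measured members, which 32 lists had. Some lists overlap, such as the fibroblast and the mesenchymal list. The gene lists, the size rule, the alternatives on pseudocount, minimum FPKM, scaling, gene value and matching, and the rule for named genes were set before the data were examined. The rule names 10 genes of the Hippo pathway and its targets, the 12 protein-coding genes with the highest and the 12 with the lowest ratio among those with an FPKM of at least 5 in either library, and from each list the 4 members with the largest absolute ratio. The value of 1 gene that the rule names is not reported here. Other named genes were chosen after their values were seen.

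Alternatives used pseudocounts of 0.1 and 5, no minimum FPKM or one of 5, both libraries scaled to the same sum, ratios centred on their median, the most abundant entry of a name, an absolute log2 ratio of 2, protein-coding genes alone, random lists not matched on expression and the list mean. Added after the data were seen were the TPM scale from the smallest step, the authors' ratio of reads with its sign turned and its offset taken out, ratios with a spline trend (6 knots) on transcript length, GC content and mean expression removed, and counts without genes whose ratios of FPKM and of reads differ by over 1. Families of genes with a shared symbol stem were also examined only after the data were seen.

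The list method was tested on simulated data made from the 14288 tested genes. Of 200 random lists of 20 genes, 5.5% stood apart with no shift and 100% with a shift of 0.3 on the log2 scale. These rates describe the simulated data alone. In the real data, random medians inside the outer 2.5% ran from -0.16 to 0.33 for the 18 YAP and TAZ targets. They ran from -0.41 to -0.03 for the 24 ATF4 genes. With ranges this wide, a shift of 0.3 could be missed. Random lists also cannot show how often genes that vary together would stand apart without a shift. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.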

Results

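Gene expression was measured by RNA sequencing in HGC-27 cells, an established line from an undifferentiated human gastric cancer, 48 h after treatment with a peptide or with a control peptide. Both peptides were carried into the cells in micelles made of the polymer PDPA. The sample titles call the peptide SOS and the series title calls it SHAP. A peptide known as SHAP is derived from STRN3, a subunit that ties the phosphatase PP2A to the kinases of the Hippo pathway, which restrains the growth-promoting co-activators YAP and TAZ. The comparison asks which genes differ in level between treated and control cells, and how the Hippo pathway and the genes under YAP and TAZ stand among them. There was 1 library per group, so no difference has a replicate check, no test was made, and every statement describes these 2 libraries. Depth was estimated, from genes apparently seen as a single read, at 2.94e7 fragments for the control library and 2.56e7 for the SOS library. Directions follow the column names of the deposited FPKM. The authors' own log2 ratio is positive where the control column is higher, so it runs control over SOS or the column names are exchanged, and in the latter case every direction given here would turn.

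Genes of the hypoxia response, of the ATF4 stress response, of cholesterol synthesis and of the mesenchymal state were higher in the SOS library. Genes of DNA replication, of a list of ribosome biogenesis and MYC targets, and of the heat shock response were lower. With a pseudocount of 1, the highest ratio among protein-coding genes with an FPKM of at least 5 in either library was that of CA9. This carbonic anhydrase at the cell surface, a marker of hypoxia, was at an FPKM of 2.93 in control and 32.4 in SOS, an 11.1-fold difference. Some genes with less in control had a larger plain fold. HSPA8, the constitutive HSP70 chaperone, stood at 2684 in control and 807 in SOS, 3.33-fold lower. Of 14288 genes with an FPKM of at least 1 in either library, 534 were higher in SOS by a log2 ratio of at least 1 and 235 were lower by as much, with a pseudocount of 1 added to both values. The higher genes were 69.4% of the 769 past this size. The split moved with scaling: with both libraries scaled to the same sum it was 983 higher and 185 lower (84.2% higher), and on a TPM scale taken from the smallest step of the values it was 825 and 190 (81.3% higher). Scaling to the same sum moved the median log2 ratio of all tested genes from -0.05 to 0.16. Gene lists are therefore placed against random lists of the same size and expression from the same 2 libraries, which carry the same shift. The ratio also fell with expression, from a median of 0.22 in the 20% of genes with the lowest mean level to -0.34 in the 20% with the highest.

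**Figure D1:**
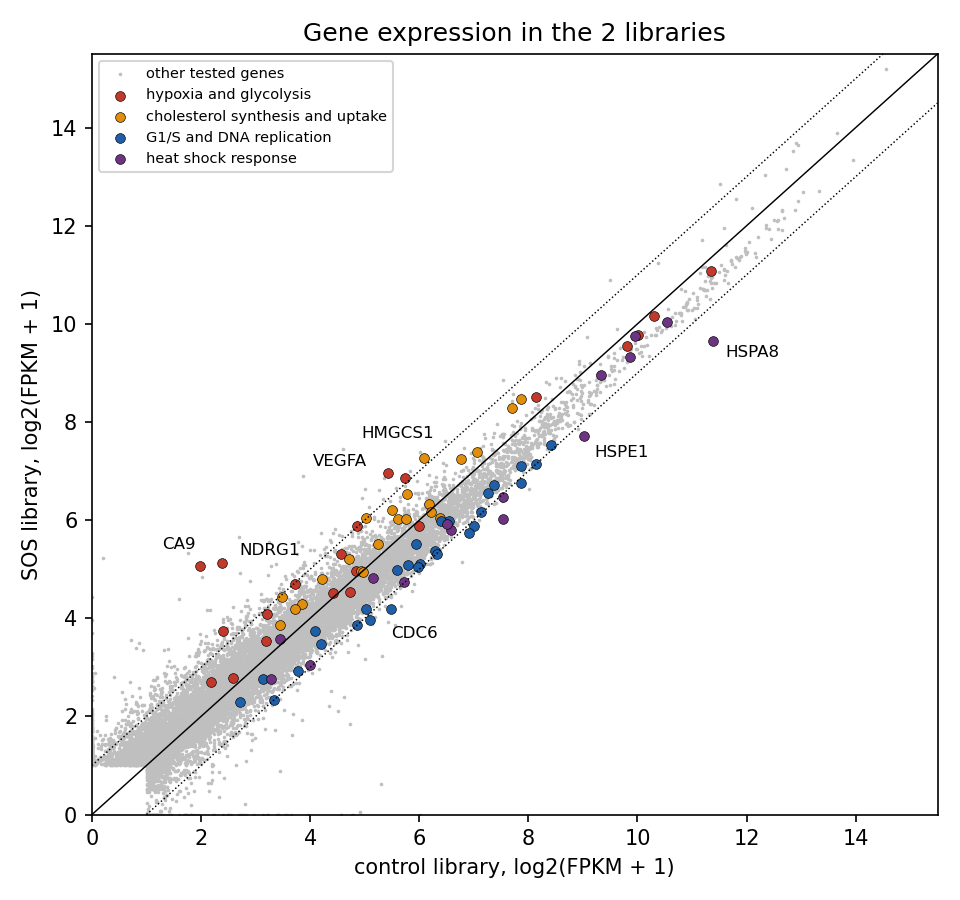
Each point is 1 of 14288 genes, with log2(FPKM + 1) in the control library on the horizontal axis and in the SOS library on the vertical axis, and the members of 4 gene lists are coloured. The solid line marks equal values and the dotted lines a log2 ratio of 1 either way; CA9, NDRG1 and VEGFA lie above the upper dotted line and HSPA8, HSPE1 and CDC6 below the lower one.

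With the minimum FPKM of 1, the lists of Hippo pathway genes and of YAP and TAZ targets stood within the central range of random lists. Single members differed in both directions. STRN3 (chromosome 14, 30893799 to 31026401, GRCh38) had an FPKM of 7.54 in control and 7.54 in SOS. The Hippo kinases STK3 and STK4 stood at 7.54 and 7.12 in control and at 7.96 and 6.87 in SOS. YAP1 (chromosome 11, 102110461 to 102233423) was at 35.3 and 37.9, and WWTR1, which encodes TAZ, at 12.5 and 12.9. None of the 18 measured target genes of YAP, TAZ and their TEAD partners passed the size rule, which understates differences at low level. Their median log2 ratio was 0.20, at the 82.6 percentile of the random lists, with 12 members above 0. Restricted to genes with an FPKM of at least 5 in either library, the list reached the 97.8 percentile, on the higher side. Among classical targets, the matricellular CYR61 (CCN1) was at 4.31 and 3.82, CTGF (CCN2) at 0.128 and 0.279, and AMOTL2, a feedback inhibitor of YAP, at 1.72 and 1.20. ANKRD1 was near 0 in both libraries. The receptor kinase AXL was at 6.37 in control and 10.3 in SOS, TGFB2 at 2.10 and 4.19, the matrix protein CCDC80 1.69-fold higher in SOS, and the growth factor carrier IGFBP3 at 4.09 and 1.72. By the authors' ratio of reads, turned to SOS over control with its offset removed, IGFBP3 came to -1.30 and TGFB2 to 1.09. The 29 measured Hippo kinases, adaptors and TEAD factors had a median of -0.03 (percentile 53.5), which turned positive with both libraries scaled to the same sum. TEAD4 was at 38.5 and 23.6, TEAD1 at 9.12 and 12.7, the TEAD cofactor VGLL4 at 20.5 and 33.3, and the adaptor WWC1 at 9.60 and 6.63. The 19 subunits of PP2A and of the STRIPAK complex, to which STRN3 belongs, had a median of -0.12 (percentile 51.5), which also turned positive under that scaling. The catalytic subunit PPP2CB was at 39.1 and 27.7, the cortactin-binding CTTNBP2 at 3.95 and 5.18, and the scaffold subunits PPP2R1A at 108 and 89.7 and PPP2R1B at 17.1 and 14.0.

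Hypoxia-response genes formed the list with the most members higher in SOS by the size rule. Of 21 measured hypoxia and glycolysis genes, 6 were higher in SOS by the size rule and none was lower, with a median of 0.38 at percentile 100. After CA9 (chromosome 9, 35673856 to 35681159) came NDRG1, a stress-responsive gene, at 4.24 in control and 33.8 in SOS (7.97-fold), and VEGFA, the main angiogenic growth factor, at 42.1 and 124 (2.95-fold). PFKFB4, which makes an activator of glycolysis, was at 4.26 and 12.5. The glycolytic enzymes LDHA, ENO1 and TPI1 did not share this direction, with log2 ratios of -0.25, -0.27 and -0.26. NDUFA4L2, another gene of the hypoxia response, lay outside the list and was at 23.3 in control and 174 in SOS (7.46-fold).

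Of 24 genes of the integrated stress response, the list that holds the transcription factor ATF4 and its targets, 22 were higher in SOS, with a median of 0.47 at percentile 100. Past the size rule were 3 of them: SLC7A11, the cystine importer, at 3.25 and 11.5 (3.55-fold), the mTORC1 inhibitor DDIT4 at 184 and 460, and CHAC1, which degrades glutathione, at 10.6 and 27.9. The stress protein NUPR1 was at 43.0 and 82.9. ATF4 itself was at 463 and 499. The cholesterol pathway showed a similar spread, with 19 of 22 genes above 0, a median of 0.45 and percentile 100. HMGCS1, an early enzyme of the mevalonate pathway, was at 66.9 and 152 (2.27-fold) and the sterol oxidase MSMO1 at 31.4 and 65.1, both past the size rule. STARD4, a sterol carrier, was at 10.1 and 20.5, and INSIG1, the sterol-sensing brake on SREBP, at 54.0 and 91.0.

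Most genes of the mesenchymal list were higher in the SOS library. Of 19 mesenchymal genes, 15 were above 0 and 2 passed the size rule, with a median of 0.41 at percentile 100. These were LOX, which crosslinks collagen, at 17.3 and 52.2 (3.01-fold), and COL5A1 at 22.2 and 51.2. COL1A1 was at 210 and 379, and the mesenchymal transcription factor ZEB1 at 12.9 and 23.9, while VIM, the vimentin gene, stood at 3161 and 3140 and the matrix genes THBS1 and MMP14 had ratios of -0.23 and -0.15. Markers of fibroblasts and stromal cells moved with this group: 9 of 10 were above 0 and the median was 0.63 at percentile 100. POSTN, a matrix protein, was at 28.0 and 61.3, and the growth factor receptors PDGFRA and PDGFRB at 4.24 and 8.09 and at 2.51 and 5.07. The fibroblast list shares COL1A1 and COL3A1 with the mesenchymal one. Of 6 measured epithelial genes 5 were above 0, with a median of 0.48 at percentile 95.2, and 62.1 with no minimum FPKM. OCLN was at 0.952 and 2.13, MUC1 at 3.77 and 6.08, CLDN7 at 4.64 and 6.96, and DSP at 4.22 and 6.16.

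DNA replication genes were lower without exception. All 28 measured genes of the G1/S transition had a ratio below 0, also with both libraries scaled to the same sum, and 8 passed the size rule, with a median of -0.87 at percentile 0. CDC6 (chromosome 17, 40287633 to 40304657), which loads the replicative helicase, was at 43.7 in control and 17.2 in SOS, 2.54-fold lower. The flap endonuclease FEN1 was at 119 and 52.3, and the replication factors MCM10 and MCM5 at 33.3 and 14.6 and at 127 and 57.7. Genes of G2 and mitosis did not share this direction. Their median was 0.03, with 14 of 26 above 0 as deposited and 25 with both libraries scaled to the same sum, at percentile 99.9 of lists matched on expression but 75.3 of lists not matched. HMMR, a spindle protein, was at 7.62 and 19.8 and passed the size rule, and the kinetochore proteins CENPE and CENPF were at 2.48 and 5.71 and at 29.3 and 55.0. TOP2A was at 61.2 and 110. Of 9 measured replication-dependent histone genes 6 were above 0, with a median of 0.39 at percentile 96.8. This depended on which members were kept: with no minimum FPKM the median lay below 0 at percentile 9.94, and 29 genes with HIST symbols, grouped after the data were seen, stood at percentile 64.95. HIST1H4H was at 1.32 and 3.79, HIST2H2AC at 3.80 and 7.85, HIST1H2AG at 1.04 and 1.84, and HIST1H1C at 18.3 and 9.25. HIST1H4H came to 0.59 by the authors' ratio of reads, against 1.05 by FPKM.

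Genes of the list that joins ribosome biogenesis and MYC targets, called the ribosome biogenesis list, were lower as well. All 21 had a ratio below 0, 4 of them past the size rule, with a median of -0.72 at percentile 0. The nucleolar protein NOP16 was at 117 in control and 50.7 in SOS, POLR1B, a subunit of RNA polymerase I, at 40.3 and 18.1, ODC1, the first enzyme of polyamine synthesis, at 168 and 80.1, and RRP9 at 32.4 and 15.7. All 40 listed cytosolic ribosomal protein genes were below 0 too, with a median of -0.52 at percentile 4.33 of lists of equally abundant genes. The wider RPS and RPL families, grouped after the data were seen, stood at 0 and 1.93. RPL37A was at 2186 and 1273, RPL32 at 1813 and 1069, RPS23 at 6412 and 3870, and RPS14 at 1650 and 1011.

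Heat shock genes were lower in 14 of 15 cases. Their median was -0.58 at percentile 0.24, and 4 passed the size rule. After HSPA8 (chromosome 11, 123057489 to 123063230), the inducible HSP70 gene HSPA1B was at 184 in control and 64.0 in SOS (2.87-fold lower), the mitochondrial co-chaperonin HSPE1 at 516 and 209, and the co-chaperone DNAJA1 at 185 and 88.3. HSPA1B shares nearly all of its sequence with HSPA1A, so their separate values are uncertain. Chaperones of the endoplasmic reticulum had a median of -0.07, which turned positive with both libraries scaled to the same sum. Matched on expression they stood at percentile 97.8, a place they lost in 8 of the 11 alternatives that can move it. HSP90B1 was at 145 and 217, HSPA5 at 228 and 151, CALR at 554 and 370, and SDF2L1 at 122 and 77.4.

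Transcripts of the mitochondrial genome were mostly higher in SOS. Those of the nuclear genes for the same respiratory complexes were lower, but hardly more so than equally abundant genes. Of the 13 mitochondrial coding genes, 11 were above 0, with a median of 0.53 at percentile 100, and their share of the summed FPKM was 9.84% in control and 16.8% in SOS. MT-ND4L was at 7698 and 13164, MT-ND4 at 3602 and 5943 and MT-ND3 at 5154 and 8414. The coding genes below 0 were MT-ND6, on the other strand, at 265 and 133, and MT-CYB, on the same strand as the higher ones, at 1351 and 977. By the authors' ratio of reads MT-ND6 differed little, at -0.02. All 31 nuclear genes of oxidative phosphorylation were below 0 as deposited, and 27 of them were not above 0 with both libraries scaled to the same sum. Their median of -0.49 was at percentile 9.28, inside the central range, against a median of -0.41 for lists matched on expression. NDUFS3 was at 164 and 79.3, past the size rule, UQCRQ at 252 and 141, NDUFB5 at 72.1 and 41.5, and NDUFA9 at 122 and 71.8.

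In the list of non-polyadenylated and nuclear RNAs the small non-polyadenylated ones were lower, and both long nuclear RNAs were higher. The median over 9 genes was -0.60, the value of the spliced host gene GAS5, at percentile 0.875, which moved inside the central range by the ratio of reads (6.765) and with the trend on length, GC content and expression removed (3.82). By the size rule 4 were lower and 1 was higher. RMRP was at 13.4 and 2.79, the signal recognition particle RNAs RN7SL1 and RN7SL2 at 257 and 98.9 and at 110 and 34.2, and RN7SK at 24.9 and 8.96. The nuclear RNAs NEAT1 and MALAT1 were at 55.6 and 24.6 in control and at 127 and 42.1 in SOS. RN7SL1 and RN7SL2 are near-identical copies, so the split between them is uncertain. Of 38 measured genes annotated as miscellaneous RNA, mostly scarce copies of these RNAs at 0 in 1 library, 20 were higher and 14 lower by the size rule, with a median of 1.04. This group is sensitive to how messenger RNA was selected, and it differed beside all of the groups above. Housekeeping genes had a median of -0.33 at percentile 69.2, with TFRC, the transferrin receptor, at 72.1 and 33.4, RPLP0 at 4043 and 2770, ACTB at 1878 and 1303, and PPIA at 6035 and 4348.

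**Figure D2:**
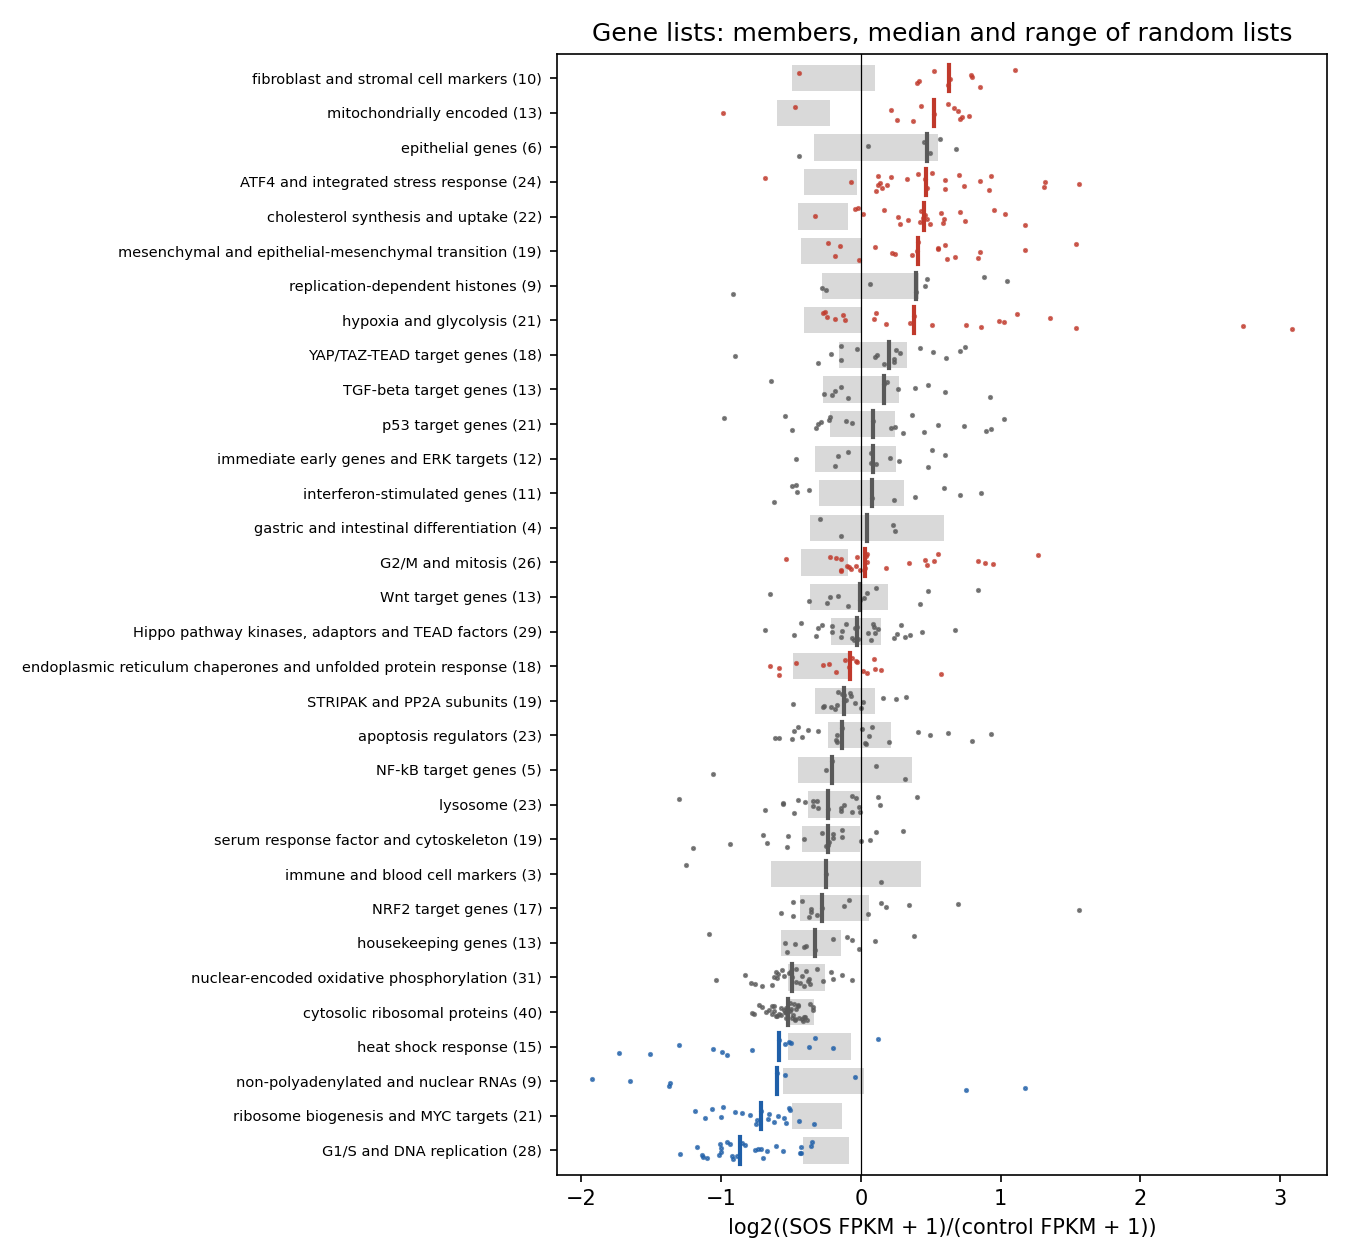
Each line of points is 1 gene list, with the number of measured members in brackets, plotted by log2((SOS FPKM + 1)/(control FPKM + 1)); the vertical bar is the list median and the grey band holds the central 95% of medians of 10000 random lists matched on expression. Of the 32 lists, 8 are drawn in red at the high end and 4 in blue at the low end, with the G1/S list lowest at a median of -0.87.

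The remaining lists stayed within the central range of random lists. Target genes of p53 had a median of 0.09 (percentile 76.4), with TP53INP1 past the size rule at 0.357 and 1.77, AEN at 21.8 and 10.6, BBC3 at 2.46 and 5.61, and GDF15 at 2.19 and 4.93. With a minimum FPKM of 5 that median was negative (percentile 24.9), as it was with the trend removed. Apoptosis regulators had a median of -0.14 (percentile 15.6), which turned positive with both libraries scaled to the same sum. XIAP was at 3.67 and 7.12, BMF at 1.53 and 2.91, and BAK1 at 16.7 and 10.6. By the ratio of reads XIAP came to only 0.23, against 0.80 by FPKM. For NRF2 targets the median was -0.28 (percentile 25.1), with AKR1C1 at 0.742 and 1.82, TXNRD1 at 59.8 and 39.9, and FTL at 737 and 527. SLC7A11, which this list shares with the ATF4 list, passed the size rule at 3.25 and 11.5. Lysosomal genes had a median of -0.23 (percentile 37.7), with GPNMB past the size rule at 57.1 and 22.5, CTSL at 53.2 and 32.7, ATP6V0D1 at 37.6 and 25.2, and MCOLN1 at 11.6 and 7.55. Interferon-stimulated genes had a median of 0.08 (percentile 73.6), with IFI44L at 28.4 and 52.3, IFI44 at 1.33 and 2.80, ISG15 at 19.0 and 12.1, and IRF9 at 4.64 and 7.54. With a minimum FPKM of 5 the interferon median was negative, at percentile 4.73. Of the NF-kB targets 5 were measured, with a median of -0.21 (percentile 24.9), and the chemokine CCL2 passed the size rule at 22.6 and 10.3. The inhibitor NFKBIA was at 16.5 and 20.8, NFKB1 at 12.1 and 9.99, and IRF1 at 6.45 and 5.45. With no minimum FPKM the median of this list was positive (percentile 53.9). Immediate early genes and ERK targets had a median of 0.09 (percentile 82.3), with JUN at 2.66 and 4.11, ATF3 at 5.18 and 8.41, ETV5 at 3.52 and 5.44, and DUSP1 at 4.31 and 2.86. ETV5 came to 0.18 by the ratio of reads, against 0.51 by FPKM. Wnt targets had a median of -0.01 (percentile 75), positive with both libraries scaled to the same sum, with BMP4 at 3.42 and 6.91, CCND1 at 83.5 and 52.8, TNFRSF19 at 2.22 and 3.48, and NKD1 at 16.6 and 22.6. The median of TGF-beta targets was 0.17 (percentile 89.0), with SKIL at 0.787 and 2.39, ID3 at 37.3 and 23.6, LTBP2 at 1.25 and 2.41, and BMPR2 at 11.4 and 16.4. Serum response factor and cytoskeleton genes had a median of -0.24 (percentile 46.5), with ACTA2 past the size rule at 20.2 and 8.24, TAGLN at 4.14 and 1.69, FHL2 at 11.4 and 6.66, and TAGLN2 at 259 and 162. That median turned positive with the trend removed (percentile 84.1). TAGLN came to -0.38 by the ratio of reads, against -0.93 by FPKM. The 4 measured gastric and intestinal differentiation genes had a median of 0.04 (percentile 43.0), with KLF5 at 9.88 and 7.89, GATA6 at 2.55 and 3.20, CDX2 at 3.39 and 4.15, and GATA4 at 7.57 and 6.76, and a median below 0 with the trend removed. Only 3 of 11 immune and blood cell markers were measured, with a median of -0.25 (percentile 40.6), which turned positive with no minimum FPKM and with the trend removed. Among them, the near-identical globin copies HBA1 and HBA2 were at 224 and 188 and at 34.2 and 13.8. No endothelial marker reached an FPKM of 1. Among metallothioneins, MT1X was at 157 and 124 and MT2A at 322 and 271.

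The protein-coding genes with the most extreme ratios were mixed in kind, and at the low end the ratio of FPKM often differed from the ratio of reads. After CA9, the highest 12 held CDKL1 (5.47 and 49.5), NDUFA4L2, SMIM11B (0.037 and 6.41), ANKRD18A (0.650 and 10.7), AC096887.1 (0 and 6.04), ANKRD36C (2.02 and 20.1), NDRG1, CACNA2D4 (0.815 and 10.2), MT4 (3.31 and 17.0), the prostaglandin D synthase PTGDS (1.49 and 9.25) and the heat shock factor HSF4 (3.46 and 17.1). The lowest 12 held USP41 (29.2 and 0.041), GABRB1 (25.5 and 2.62), AC006538.2 (6.09 and 0), HIST1H4K (5.61 and 0), ZFP91-CNTF (5.99 and 0.164), LRMDA (9.91 and 0.862), BICRAL (23.7 and 4.26), RBMS2 (30.9 and 8.04), PYURF (6.09 and 1.13), HSPA8, POLE4 (46.1 and 13.6) and SLC12A5 (11.9 and 3.17). By the ratio of reads taken from the authors' deposited table, 9 of the 11 highest genes that have one kept a log2 ratio of at least 1, and 5 of the 10 lowest that have one kept -1 or less. Among those that kept it, MT4 and GABRB1 were not marked as significant by the authors and may rest on few reads. CDKL1 came to 0.68 and ANKRD18A to 0.77 by that ratio, USP41 to -0.85, LRMDA to -0.85, BICRAL to -0.29, RBMS2 to -0.01 and SLC12A5 to 0.08. SMIM11B, USP41, ANKRD18A, ANKRD36C and HIST1H4K have close copies elsewhere in the genome and ZFP91-CNTF is a read-through of neighbouring genes, so their values are uncertain. By contrast, CA9 came to 3.57, NDRG1 to 2.74, VEGFA to 1.31, HSPA8 to -1.60 and CDC6 to -1.26.

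In the authors' deposited table, 1098 genes were marked as significant, 752 higher in SOS and 346 higher in control by the sign of the authors' ratio. The authors' own label of direction calls the 346 up and the 752 down. Every marked gene had an absolute log2 ratio of at least 1 and an adjusted p under 0.001, and every gene that met both was marked. The authors' ratio appeared to be one of reads not scaled for depth. With its median offset of 0.152 from the FPKM ratio taken out, the same limits gave 970 genes higher in SOS and 173 higher in control, a share of 84.9% in place of 68.5%. A p from 1 library against 1 compares those libraries, not the treatments. Of the 769 genes past the size rule by FPKM, 334 were among those marked in the authors' deposited table, and 322 had a ratio of reads that differed by over 1 on the log2 scale or had none.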

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

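The TPM scale from the smallest step, the ratio of reads, the removal of a trend and the counts without discordant genes were chosen after the data were seen. Centring on the median shifts all genes alike and cannot move a percentile. Scaling to the same sum and the TPM scale shift abundant genes nearly alike, and the most abundant entry changes few genes. These 3 could therefore hardly move the place of a list of abundant genes. In the 11 alternatives other than centring, the hypoxia, ATF4, cholesterol, mesenchymal, fibroblast and mitochondrially encoded lists stayed in the upper 2.5% of random lists, with percentiles from 99.87 to 100. The G1/S, ribosome biogenesis and heat shock lists stayed in the lower 2.5%, from 0 to 0.41. The counts of genes depended more on the choices, by construction for the pseudocount, the minimum and the size rule. They were 1094 higher and 442 lower in SOS with a pseudocount of 0.1, 99 and 64 with 5, 273 and 126 with a minimum FPKM of 5, 51 and 38 at an absolute log2 ratio of 2, and 245 and 99 for protein-coding genes alone. Without genes with discordant ratios they were 336 and 111. With both libraries scaled to the same sum there were 983 higher genes, 825 on the TPM scale and 926 by the ratio of reads, with lower counts of 185, 190 and 303. Ratios centred on the median gave 646 and 180, and with the trend removed 402 and 234.

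The list of endoplasmic reticulum chaperones and unfolded protein response left the upper 2.5% at 96.68 with no minimum, 97.17 with a minimum of 5, 97.41 scaled to the same sum, 97.34 on the TPM scale, 94.05 by reads, 77.17 with the trend removed and 87.69 by the mean, and lay at 42.5 among unmatched lists. Ribosomal proteins entered the lower 2.5% at 1.31 with no minimum, 1.52 by reads, 0.07 with the trend removed, 0 unmatched and 0.11 by the mean. Nuclear oxidative phosphorylation genes did so at 0.01 unmatched and 1.02 by the mean. The non-polyadenylated and nuclear RNAs left it at 6.765 by reads and 3.82 with the trend removed. The YAP and TAZ targets came to 97.76 with a minimum of 5. Among unmatched lists, G2 and mitosis genes came to 75.34, epithelial genes to 98.65 and histones to 98.48. With no minimum FPKM these last lists came to 62.12 and 9.94, and the histone median turned below 0. For the unmatched lists the fall of the ratio with expression enters the place of a list; otherwise the cause was not tested. Among the named genes, SLC12A5 turned from -1.63 to 0.077 by reads. No paired analysis was possible because each group has 1 library. The planned counts of transcripts and of transcript shares were not run, since the table has 1 entry per gene. For want of counts and of repeat cultures, neither counting error nor culture error could be attached to a value.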

Other observations

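The symbol families, the gene types, the check on exchanged column names and the check on differences between cultures were chosen after the data were seen. A few genes outside the lists are named here because their values were seen to be high in the SOS library, so they add no support to any list, and genes of the hypoxia and ATF4 responses that were not higher were not counted. The secreted hormone STC1 was at an FPKM of 6.16 in control and 19.8 in SOS, the lipase inhibitor ANGPTL4 at 12.7 and 26.0, PPFIA4 at 6.06 and 15.1, the stress hormone FGF21 at 2.77 and 8.87, and the activin subunit INHBE at 13.7 and 31.5. CCNG2, a cyclin G linked to cell cycle arrest, was at 4.27 and 14.9. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 were 2.67-fold and 2.51-fold higher in SOS, more than any mitochondrial coding gene.

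Among 197 families of protein-coding genes with a shared symbol stem, 8 stood in the upper and 20 in the lower 2.5% of random lists. If genes varied independently, 4.9 would lie on each side. Genes of a family can vary together or be near-identical copies, and some families repeat genes of the lists above. The number 4.9 is therefore no reference for these families. The collagen genes (COL) had a median log2 ratio of 0.56 over 23 genes, 19 of them above 0, and the centrosomal proteins (CEP) 0.32 over 33 genes, 29 of them above 0. The lower families included the MRPL proteins of the mitochondrial ribosome, all 49 below 0 with a median of -0.49, the proteasome subunits PSMB (-0.65) and PSMD (-0.60), the mitochondrial import proteins TOMM (-0.72) and TIMM (-0.53), the nucleoporins NUP (-0.46), the caspases CASP (-0.34), and the cytosolic ribosomal proteins RPS (-0.54) and RPL (-0.52). All 9 cancer-testis antigen genes of the MAGEA family were lower, with a median of -0.81. Some of these are close copies, so they may not be 9 separate measurements. Aminoacyl-tRNA synthetases, several of which are ATF4 targets, stood high for their level (percentile 99.8, median -0.08). The multicopy families NBPF, NPIPB and GOLGA, with medians of 0.42, 0.49 and 0.41, stood high too, as did unprocessed pseudogenes (median 0.28 over 101 genes), while processed pseudogenes stood low (median 0.02 over 253 genes, against 0.16 in matched lists).

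The higher hypoxia, ATF4, cholesterol and mesenchymal lists form the first pattern weighed. A trend of the ratio with annotated transcript length, GC content and expression level is argued against as the whole cause. With that trend removed, which took out 14.6% of the variance, each of the 4 lists was still at percentile 100. The random lists were already matched on expression, so for that part the removal repeats the matching. For length and GC content the trend was weak to begin with (Spearman rho of 0.07 and -0.10 across genes). Both were medians over annotated transcripts, so a trend with the properties of the transcripts expressed was not tested. The way reads were split among a gene's transcripts when FPKM was made is argued against too, since each of the 4 was at percentile 100 by the authors' ratio of reads. A response to the peptide stays open as a hypothesis, and so does a denser or older culture with less oxygen and nutrient, which might raise hypoxia and ATF4 targets and was not tested.

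The lower G1/S and ribosome biogenesis lists form the second pattern. Both were at percentile 0 with the trend on length, GC and expression removed. This argues against a trend of the ratio with those properties as annotated, but not with those of the transcripts expressed. Here too the random lists were already matched on expression, so the removal adds little. Both were at percentile 0 by the authors' read ratio, which argues against the way reads were split among a gene's transcripts when FPKM was made. The lower level of replication genes may reflect fewer cells in S phase in the SOS culture, a hypothesis that expression alone does not settle, since genes of G2 and mitosis were not lower with them.

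The lower heat shock list is the third pattern. It stood at percentile 0 with the trend removed and at 0.24 by the ratio of reads. Neither the trend with annotated properties nor the split of reads among transcripts therefore accounts for it. As above, the removal of the trend adds little to the matching on expression. Less protein stress in the SOS culture, or more of it in the control culture, could give such a list, and nothing here decides between these.

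For all of these patterns, a difference between the 2 cultures other than the peptide cannot be told apart from an effect of the peptide, because the number of libraries per group is 1. An exchange of the names of the 2 FPKM columns likewise stays open: the authors' ratio correlated at 0.93 across genes with control over SOS, which is what an exchange would give and also what a ratio written as control over SOS would give. The authors' label of up on marked genes that are higher in the control column would follow from either. If the names are exchanged, the peptide-treated cells might be those with higher replication, ribosome biogenesis and heat shock genes.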
